A study of Homo sapiens with 960 samples.

How the data were processed

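White blood cells (WBC), the nucleated cells of blood, were profiled by indexing chromatin immunocleavage sequencing, in which a nuclease bound to an antibody cuts the chromatin that carries a histone mark and barcodes are added in rounds so that reads can be assigned to single cells. The labels give 480 libraries for H3K4me3, a mark of active promoters, and 480 for H3K27me3, a mark laid down by Polycomb complexes. Per the labels' protocols for the H3K4me3 libraries, cells were fixed with disuccinimidyl glutarate for 45 minutes and with formaldehyde for 10 minutes, barcoded in wells, pooled, and redistributed at 30 nuclei per well. The DNA was then amplified by 12 and 16 cycles of PCR and cut from a gel between 200 and 500 bp.

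The authors deposited 4 tables of raw counts, whole numbers of reads per region (rows) and cell (columns), without normalization, and 3 lists of regions. Per the submitters' processing notes, Bowtie2, SICER and bedtools were used with the build hg18. Their versions, settings and order, the filter that selected cells and the treatment of PCR duplicates are not given in the sources used here. Per the file headers, the columns of the H3K4me3 region table carry the library, the barcode and hg18. The other 3 tables have no header, and each mark was therefore treated as 1 pooled sample when the marks were compared. H3K4me3 values were also computed in each of 5 sets of libraries.

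The list of H3K4me3 regions held 52798 regions, all 3000 bp wide. The list of H3K27me3 regions held 79100 regions with a median width of 6000 bp (range 200 to 379800 bp). The list of bivalent domains, here regions where the lists of both marks meet, held 25951 domains of 100 to 3000 bp. Each of them equalled the intersection of an H3K4me3 region with an H3K27me3 region (25951 of 25952 intersections). No cell was measured for both marks, so a domain need not carry both in the same cells. The rows of the count tables followed the chromosome number and not the alphabetical order of the lists. With the lists sorted by number, summed H3K4me3 counts of the 16610 domains that equal an H3K4me3 region correlated with the counts of that region (Pearson's r of log2 totals 0.987, against 0.125 in the listed order), and no cell had fewer reads in the domain table than in the region table. Both tables of a mark listed the cells in the same order.

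For domains identical to an H3K4me3 region the H3K4me3 count was a median of 1.418 times that of the region table, so the 2 tables of H3K4me3 were not counted alike. Windows wider than the listed domain would give this, and so could another treatment of duplicate reads. These were not told apart. For the 641 domains identical to an H3K27me3 region the H3K27me3 count was a median of 0.52 times that of the region table, so the 2 tables of that mark were not counted alike. Domain counts of neither mark were proportional to domain length. In the H3K27me3 region table the median summed count was 1434 for regions up to 3000 bp and 2209.5 for regions over 30000 bp, so the counting window was close to fixed. Such windows can overlap, and summed H3K27me3 counts per cell are therefore sums over windows and not numbers of distinct reads.

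The H3K4me3 table held 7798 cells with 16659384 counts, and that of H3K27me3 held 9207 cells with 135600639 counts. Column names put the H3K4me3 cells in 430 libraries, in 5 sets of 86 by the library titles. The other 50 labelled H3K4me3 libraries had no cell in the table. No doublet caller was run, so columns that hold 2 nuclei with the same library and barcode were not flagged. With 96 barcodes and the observed 18.13 cells per library, an expected 10.1% of used barcodes held 2 or more nuclei, and 14.8% at the loaded 30 nuclei. Variance ratios and clusters were recomputed without the deepest 10% of cells, and the other results were not.

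Levels, ratios, variation and clusters were computed on autosomes only, with positions given as in the deposited lists (hg18). No genome or annotation of hg18 was used here. The gene table at hand was built on GRCh38.p14, and no coordinates were converted, so regions carry no gene names, the marker lists fixed in advance could not be applied, and clusters have numbers and no cell types.

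Cells are not replicates, H3K27me3 cells carry no library names, and nothing in the labels says that the sets of H3K4me3 libraries are biological replicates. No p-values are given between marks, clusters or cells, and the text names regions by rules of size that were fixed before the data were examined. These rules take the 5 domains with the highest and the 5 with the lowest ratio of read shares, among domains with at least 100 reads in the dominating mark. They also take the 5 domains with the largest variance ratio per mark, among domains with at least 0.02 reads per cell, and the 3 regions per cluster with the largest fold, among regions with at least 100 reads. Ratios and folds have exact Clopper-Pearson 95% intervals from the counts, and shares of cells have exact binomial 95% intervals. PCR reads without molecular identifiers are not independent molecules, so all intervals cover counting error only, and variance ratios include any variance from duplicate reads. Correlations across domains are Spearman's rho with the 95% range of 200 bootstrap draws of domains. Domains are not independent replicates, and no p-value is given.

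Overlap was the number of H3K4me3 regions that share at least 1 bp with an H3K27me3 region (bedtools 2.31.1), beside 100 random placements of the regions within their chromosome. The relation of levels across domains used reads per kb, as fixed in advance, and was repeated without division by length because the counts were not proportional to it. The ratio of shares divided a domain's share of all H3K4me3 domain reads by its share of all H3K27me3 domain reads. Domination meant a ratio of at least 4 or at most 0.25 with at least 50 reads over both marks. The variance ratio was the observed sum of squared deviations of a domain's counts from the domain total times each cell's share of reads, divided by the sum that Poisson counting gives. On simulated counts without added variation its median was 0.998 for H3K4me3 and 1.0001 for H3K27me3 over 2000 domains. With an added squared coefficient of variation of 0.5 it was 1.0339 against 1.0312 expected for H3K4me3, and 1.1241 against 1.1196 for H3K27me3.

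Clusters came from binarised autosomal regions with reads in at least 50 cells, TF-IDF weights, a truncated singular value decomposition with 30 components, a graph of 15 nearest neighbours and the Leiden algorithm at resolution 0.5. Components with a correlation over 0.5 in size with log depth were left out, which kept 28 components for H3K4me3 and 29 for H3K27me3. Clusters were made again from odd-numbered or even-numbered autosomes, matched to the main clusters by their Jaccard index, and used to give each region a fold from cells clustered without its own chromosome (held-out fold). The log2 folds of clusters used a prior of 0.5 counts. In simulated cells with the real depths and no groups, 1 cluster was found for each mark. A simulated group of 10% of cells with 200 regions raised 4-fold was recovered with an adjusted Rand index of 0.9328 in 7798 H3K4me3 cells and 0.6009 in 9207 H3K27me3 cells. With 8-fold the index was 0.9991 and 0.9769.

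Alternatives fixed in advance changed the counting of regions, the overlap, the length correction, the filters on low counts, the scaling, the ratio, the depth of cells, the resolution, the weighting of clusters (log-normalised counts and principal components of 5000 regions) and the chromosomes used. Others were chosen after seeing the data, as were the values per set of H3K4me3 libraries, the variance ratios without thinning at the domains that pass after it, and the excess squared coefficient of variation. The last is the excess of the observed over the Poisson sum of squares, divided by the sum of squared expected counts. Values per set used the clusters made from all cells and, where both marks enter, all H3K27me3 cells. The added alternatives related the clusters of both marks by held-out folds of domains, left out the domains above 10 times the median read count in both marks, kept only domains of the full 3 kb, or thinned cells before clustering to 1000 (H3K4me3) or 3000 (H3K27me3) counts. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.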

Results

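Single white blood cells were profiled for H3K4me3, which marks active promoters, and for H3K27me3, which marks chromatin repressed by Polycomb complexes. The labels list 480 libraries for each mark, and the H3K27me3 cells form 1 pooled matrix with no library names, so differences between marks and between H3K27me3 clusters have no replicate check. H3K4me3 cells came from 430 libraries in 5 sets, with 1559.6 ± 81.5 cells per set (SD, n = 5 sets). A library held 18.13 ± 2.86 cells (SD, n = 430 libraries). The sets are named by library titles, and nothing in the labels says that they come from separate donors or cultures, so their spread may be technical.

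The series is about measuring histone marks in single cells, and the first question was how much of each mark was read per cell. H3K4me3 cells had a median of 1749 counts over 52798 regions (interquartile range 1095 to 2762.75), and the count lay above 0 in a median of 1654.5 regions. The set medians of counts per cell were 1744.1 ± 101.2 (SD, n = 5 sets). H3K27me3 cells had a median of 8390 counts in their regions (3165 to 19938), with a median of 7677 regions above 0. H3K27me3 depth spread more widely and reached 168804 counts in a cell, against 13610 for H3K4me3. H3K27me3 counts were taken in wide windows that can overlap, so the higher median does not measure a higher yield of reads.

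**Figure D1:**
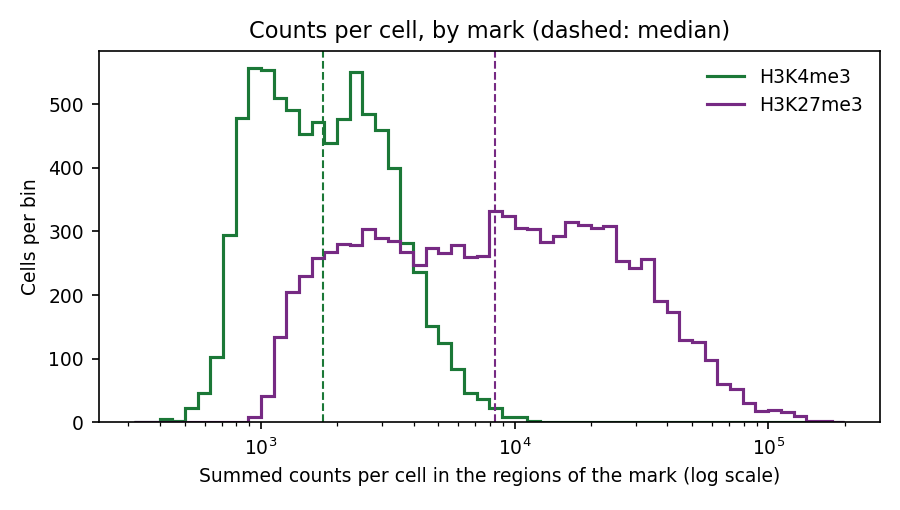
Cells per bin (y axis) by summed counts per cell in the regions of the mark (x axis, log scale) for H3K4me3 and H3K27me3, with dashed lines at the medians of 1749 and 8390 counts. The H3K27me3 cells spread over a wider range of counts than the H3K4me3 cells.

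The next comparison asked where the regions of both marks meet. Of the H3K4me3 regions, 25056 (47.5%) shared at least 1 bp with an H3K27me3 region, and 16610 (31.5%) lay fully inside one. Random placement of the H3K4me3 regions within their chromosome gave a mean of 17470.2 overlapping regions (range 17221 to 17808 in 100 placements), so the observed number was 1.43 times the random mean. Positions were drawn evenly along the chromosome, and stretches where no read can be placed were not left out. The value of 1.43 may therefore be too high. Of the H3K27me3 regions, 19606 (24.8%) touched an H3K4me3 region. The broadest H3K27me3 regions spanned 379800 bp on chromosome 5 from 72420400 to 72800199, 302400 bp on chromosome 12 from 52559200 to 52861599 and 255200 bp on chromosome 17 from 43983800 to 44238999 (hg18). Only regions with a mean of at least 0.02 reads per cell gave 14815 overlapping H3K4me3 regions, which is 42.6% of the 34797 regions that passed.

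Bivalent domains, the intersections of both lists, were then compared for the level of each mark. The 25218 autosomal domains had a median of 33.5 H3K4me3 reads per 1000 cells (21.4 to 53.7) and 102.6 H3K27me3 reads per 1000 cells (79.2 to 149.2). Per kb of domain, the levels of the marks correlated across domains with a rho of 0.409 (bootstrap range 0.398 to 0.419). With the H3K4me3 reads of 1 set at a time it was 0.406 ± 0.004 (SD, n = 5 sets). Without division by domain length rho was 0.017, and among the 16174 domains of the full 3 kb it was 0.075. Reads per kb of each mark correlated with the inverse of domain length (rho 0.575 for H3K4me3 and 0.413 for H3K27me3), so the value per kb holds a term that both marks share. From the 10% of domains with the fewest H3K4me3 reads to the 10% with the most, median H3K4me3 went from 11.3 to 121.6 reads per 1000 cells, and median H3K27me3 was 98.7 and 104.9.

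**Figure D2:**
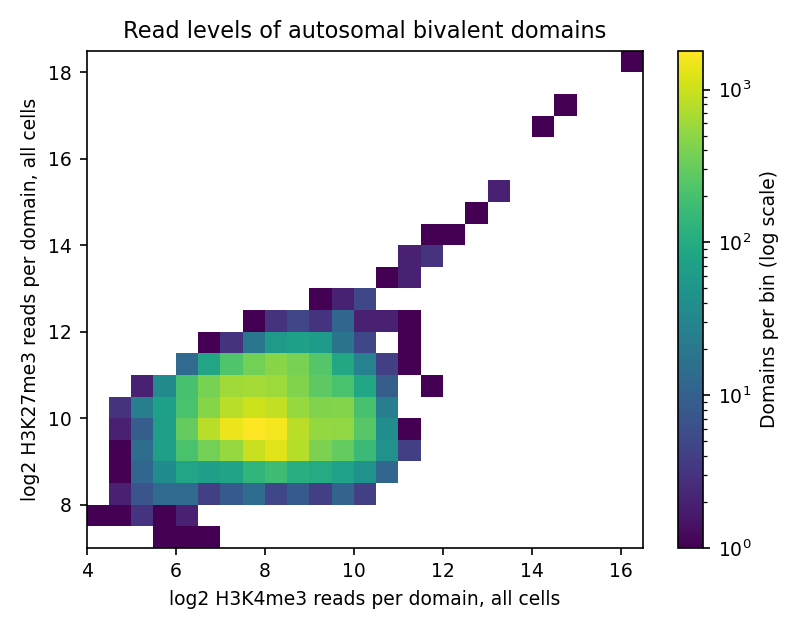
Autosomal bivalent domains binned by log2 of summed H3K4me3 reads (x axis) and log2 of summed H3K27me3 reads (y axis), with the number of domains per bin in colour on a log scale. Most domains form a cloud in which the marks are close to unrelated, and a few domains with the most reads in both marks, up to 69112 and 333577 reads, run along a line outside it.

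Domains dominated by 1 mark were found at both ends. By the ratio of read shares, H3K4me3 over H3K27me3, 995 of 25217 domains (3.9%) reached at least 4 and 1445 (5.7%) lay at or under 0.25. The middle 50% of ratios ran from 0.488 to 1.516. Across domains, read counts correlated with domain width with a rho of -0.182 for H3K4me3 and 0.401 for H3K27me3. The ratio was not checked against width, so reads counted outside a narrow domain may add to a high ratio. This was not tested. With reads scaled to all regions of each mark, 5595 domains (22.2%) passed for H3K4me3 and 19 (0.1%) for H3K27me3. Domain reads and region reads were not counted alike, however. Domains identical to a region had a median of 1.418 times its H3K4me3 count and 0.52 times its H3K27me3 count. Both raise every ratio under this scaling, so its split does not show how far domination depends on the scaling itself. The highest ratio was 14.7 (95% interval 13.4 to 16.1) on chromosome 11 from 65023500 to 65025599, from 2551 H3K4me3 and 572 H3K27me3 reads, and 14.6 ± 1.99 with the H3K4me3 reads of 1 set at a time (SD, n = 5 sets). Next were chromosome 5 from 131852000 to 131853799 with a ratio of 14.3 (12.8 to 16.0), chromosome 7 from 26205600 to 26206999 with 14.2 (12.9 to 15.6), chromosome 16 from 30102800 to 30105199 with 14.1 (12.5 to 16.1) and chromosome 20 from 46874800 to 46877799 with 13.97 (12.5 to 15.6). Their intervals overlap, and their order was not resolved at this depth. Most of these 5 domains are narrower than the full 3 kb. Under the scaling to all regions these 5 ratios were 33.96 to 35.7.

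At the other end, the lowest ratio was 0.061 (0.040 to 0.090) on chromosome 8 from 4836500 to 4839499, where 27 H3K4me3 reads stood against 1445 H3K27me3 reads. The share of H3K27me3 reads in this domain was 16.3 times that of H3K4me3 reads. The domain on chromosome 10 from 134750000 to 134752999 had a ratio of 0.073 (0.047 to 0.108). The domains on chromosome 8 from 99507100 to 99510099, chromosome 10 from 23501200 to 23504199 and chromosome 3 from 6876700 to 6879699 had ratios of 0.077 (0.050 to 0.112), 0.085 (0.059 to 0.117) and 0.085 (0.058 to 0.121). These 5 domains were all of the full 3 kb, had 25 to 37 H3K4me3 reads in all cells, and their intervals overlap. Under the scaling to all regions they stayed at or under 0.207.

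The variance of counts between cells was computed at 19659 domains with at least 0.02 reads per cell in both marks. The variance was a median of 1.044 times that expected from counting for H3K4me3 and 1.043 times for H3K27me3. Counting alone, simulated at the same domains and depths, gave a median of 0.999 for both marks, and 10438 domains (53.1%) for H3K4me3 and 9050 (46%) for H3K27me3 lay above the central 95% of the simulated values. The simulation treats each read as an independent molecule. Duplicate PCR reads would also raise the variance, and their treatment is not given, so neither the excess nor these numbers of domains show that cells differ. Both marks passed that bound at 4995 domains, against 4805.1 for independent lists. The variance ratios of the marks correlated with a rho of 0.044 (bootstrap range 0.030 to 0.057). Within single sets the H3K4me3 median was 1.037 ± 0.004 (SD, n = 5 sets). In cells thinned to 500 domain reads, 3042 domains still passed, and 22.9% of H3K4me3 and 17.8% of H3K27me3 cells had too few reads. The medians there were 1.021 and 1.011 and rho was 0.004, against 1.047, 1.045 and 0.058 in the same domains and cells without thinning.

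The largest variance ratios for H3K4me3 were 3.07 on chromosome 1 from 121184300 to 121187199, 2.47 on chromosome 6 from 58884400 to 58887399, 2.14 on chromosome 7 from 61605700 to 61608699, and 1.92 and 1.51 on chromosome 10 from 41703000 to 41705999 and from 41714400 to 41717399. For H3K27me3 the same domains on chromosomes 1, 6 and 7 led with 7.64, 5.01 and 3.86, followed by 2.69 on chromosome 10 from 41703000 to 41705999 and 2.31 on chromosome 16 from 44948100 to 44951099. All 6 domains had more than 10 times the median read count in both marks. For a given relative variation the excess of this ratio over 1 grows with the read level, so the ranking favours domains with many reads. Expressed as a squared coefficient of variation, the excess on chromosome 1 was 0.153 for H3K4me3 and 0.08 for H3K27me3, below the medians of 0.607 and 0.158 over the 19659 domains. The named domains on chromosomes 6 and 7 were below these medians too. On chromosome 10, the domain from 41703000 had 0.549 for H3K4me3 and 0.173 for H3K27me3, and the domain from 41714400 had 0.619 for H3K4me3. The domain on chromosome 16 had 0.32 for H3K27me3. The domain on chromosome 1 alone held 8.863 H3K4me3 reads and 36.231 H3K27me3 reads per cell. Thinned to 500 domain reads per cell, its variance ratio was 1.62 for H3K4me3 and 2.45 for H3K27me3.

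H3K4me3 cells fell into 4 clusters. Clusters 1 to 4 held 49.1% ± 2.7, 26.9% ± 2.4, 15.1% ± 1.1 and 8.8% ± 1.0 of cells (SD, n = 5 sets). Counting cells alone gives SDs of 1.3, 1.1, 0.9 and 0.7 percentage points between sets of this size, so the sets differed by about 2 times the counting SD in clusters 1 and 2 and by less in clusters 3 and 4. Over all cells the shares were 49.1% (95% interval 48 to 50.2), 27% (26 to 28), 15.1% (14.4 to 16.0) and 8.8% (8.2 to 9.5). Median counts per cell were 2086, 1716, 1188 and 1554. Shares of a cluster varied between libraries about as much as counting cells gives, with an SD of 7.1 percentage points for cluster 4 against 6.7.

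**Figure D3:**
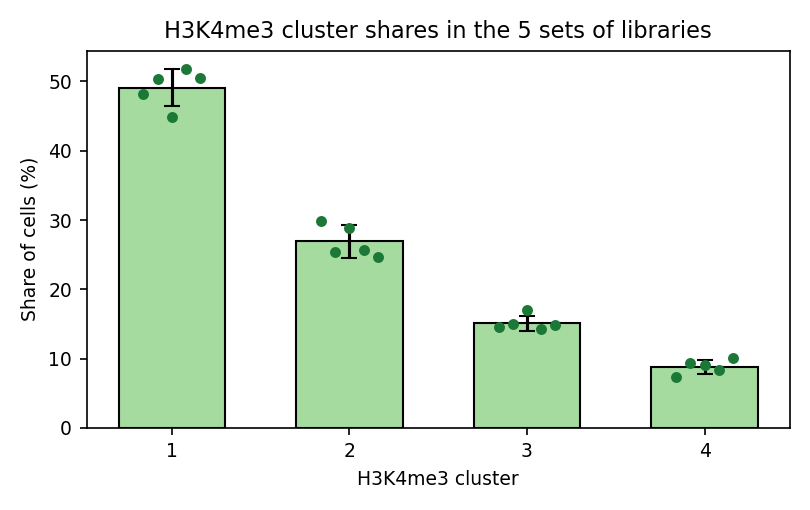
Share of H3K4me3 cells (y axis, %) in each cluster (x axis), with bars for the mean and error bars for the SD of 5 sets of libraries and a point for each set. Cluster 1 held 44.9 to 51.8% of the cells of a set and cluster 4 held 7.4 to 10.1%.

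Clusters 3 and 4 had the most distinct H3K4me3 regions. In cluster 4 the region on chromosome 18 from 28602800 to 28605799 was 15.4 times (95% interval 10.7 to 22.5) the level of all other cells, with a held-out fold of 14 from cells clustered without its own chromosome. Chromosome 9 from 82036700 to 82039699 followed at 13.4 (9.1 to 19.9, held-out 12.2) and chromosome 21 from 41523300 to 41526299 at 13.3 (9.0 to 19.7, held-out 10.8). In cluster 3, chromosome 14 from 21988500 to 21991499 was at 10.4 times the other cells (7.9 to 13.8, held-out 8.3), chromosome 1 from 160645500 to 160648499 at 9.6 (7.4 to 12.6, held-out 7.7) and chromosome 12 from 10351500 to 10354499 at 8.4 (6.9 to 10.2, held-out 7.3).

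In cluster 1 the leading H3K4me3 regions, on chromosome 2 from 108946200 to 108949199 and from 38789000 to 38791999 and on chromosome 4 from 109274500 to 109277499, had held-out folds of 2.37, 3.44 and 2.78. In cluster 2 the leading regions, on chromosome 8 from 142452900 to 142455899, chromosome 22 from 44195400 to 44198399 and chromosome 2 from 241547500 to 241550499, had held-out folds of 3.42, 1.58 and 2.24. By held-out folds over 43128 regions with at least 100 reads, 3.71% were at least 2 times higher in cluster 4 and 6.39% at least 2 times lower. These shares were 1.76% and 7.35% for cluster 3, 0.06% and 2.42% for cluster 2, and 0.52% and 0.15% for cluster 1. Low regions enter these numbers with a wide counting error. All 12 named regions, chosen for their fold over all cells, had a fold above 1 in each of the 5 sets, with as few as 13 reads of a region in a set. The fold of the first region was 15.9 ± 4.08 for cluster 4, 10.4 ± 2.06 for cluster 3, 3.35 ± 0.91 for cluster 2 and 4.04 ± 2.04 for cluster 1 (SD, n = 5 sets). Other regions spread more, with 16.3 ± 10.25 (range 6.92 to 28.8) for that of cluster 4 on chromosome 9 and 10.5 ± 4.44 (6.02 to 15.64) for that of cluster 3 on chromosome 1. Clusters from odd-numbered and even-numbered autosomes matched with an adjusted Rand index of 0.451 for H3K4me3. Log-normalised counts and principal components gave 3 clusters that shared almost nothing with the main ones (adjusted Rand index 0.019), and cells thinned to 1000 counts also gave 3 clusters, with an index of 0.186.

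H3K27me3 cells also fell into 4 clusters, with 47.3% (46.3 to 48.3), 31.9% (30.9 to 32.8), 15.7% (15.0 to 16.5) and 5.1% (4.7 to 5.6) of cells. They differed in depth, with median counts per cell of 3249, 11331, 36292 and 11178. The largest fold of a named region was 3.13, against 15.4 for H3K4me3. In cluster 1 the leading regions were on chromosome 2 from 185165800 to 185175199 at 2.29 times the other cells (2.1 to 2.5, held-out 2.13), chromosome 12 from 79850800 to 79858599 at 2.21 (2.01 to 2.42, held-out 2.07) and chromosome 12 from 38900800 to 38908999 at 2.07 (1.86 to 2.31, held-out 1.93). In cluster 2 they were on chromosome 16 from 87047400 to 87056599, chromosome 19 from 18403600 to 18412599 and chromosome 11 from 66934000 to 66944599, with folds of 1.79, 1.76 and 1.73 and held-out folds of 1.76, 1.80 and 1.72.

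Cluster 4 of H3K27me3 led on chromosome 1 from 2677800 to 2680399, chromosome 8 from 37800400 to 37811399 and chromosome 1 from 3447600 to 3458199, with folds of 3.13 (2.44 to 3.93), 2.99 (2.43 to 3.64) and 2.98 (2.35 to 3.72). Its held-out folds were 2.09, 1.70 and 1.84, below these intervals. In cluster 3, chromosome 8 from 86759400 to 86760199 and chromosome 20 from 59394000 to 59400399 and from 41218000 to 41225199 had held-out folds of 1.17, 1.27 and 1.24. Clusters 3 and 4 were matched to the same cluster from odd-numbered autosomes, so the held-out folds of cluster 3 and that of cluster 4 on chromosome 8 come from the same group of cells and do not separate these clusters. Clusters 1 and 2 were found again from odd-numbered or even-numbered autosomes with Jaccard indices of 0.73 to 0.85, while clusters 3 and 4 had indices of 0.18 to 0.59, and the odd and even clusters had an adjusted Rand index of 0.61. Across the 22 autosomes, cluster 1 was highest on chromosome 4 (median log2 fold 0.23) and lowest on chromosome 22 (-0.42).

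The last comparison asked whether bivalent domains that vary between clusters of 1 mark also vary between clusters of the other. The SD over clusters of log2 CPM (counts scaled to the same total per cluster) had a median of 0.346 for H3K4me3 and 0.244 for H3K27me3 over 19659 domains. Cells assigned to clusters at random gave 0.164 and 0.106. The clusters were made from regions that contain these domains, so SDs above the random ones follow from the clustering itself and are no separate support for it. The SDs of the marks correlated with a rho of 0.123 (bootstrap range 0.110 to 0.136), while 100 random assignments gave -0.014 to 0.017. Set side by side, the log2 folds of H3K4me3 cluster 2 and H3K27me3 cluster 4 had the strongest relation of the 16 pairs of clusters (rho 0.355), followed by H3K4me3 cluster 4 and H3K27me3 cluster 4 (rho -0.320). Given the read level of the domain in both marks, rho was 0.188 for the first of these pairs, and the pair of H3K4me3 cluster 2 and H3K27me3 cluster 3 was then the strongest with -0.201. With folds from cells clustered without the domain's own chromosome, rho was 0.277 for H3K4me3 cluster 2 and H3K27me3 cluster 4. It was -0.247 for H3K4me3 cluster 4 and H3K27me3 cluster 4. H3K4me3 cluster 2 and H3K27me3 cluster 3, with -0.250 before, had 0.092, from -0.061 on odd-numbered and 0.25 on even-numbered chromosomes. On the even-numbered ones the folds of H3K27me3 clusters 3 and 4 came from the same group of cells. The 0.092 therefore does not show a change of sign for cluster 3. H3K27me3 cluster 4 was poorly found again from odd-numbered or even-numbered autosomes (Jaccard indices 0.38 and 0.27), and from the odd-numbered ones it was not separate from cluster 3. The clusters come from separate pools of cells, and no cell was measured for both marks.

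**Figure D4:**
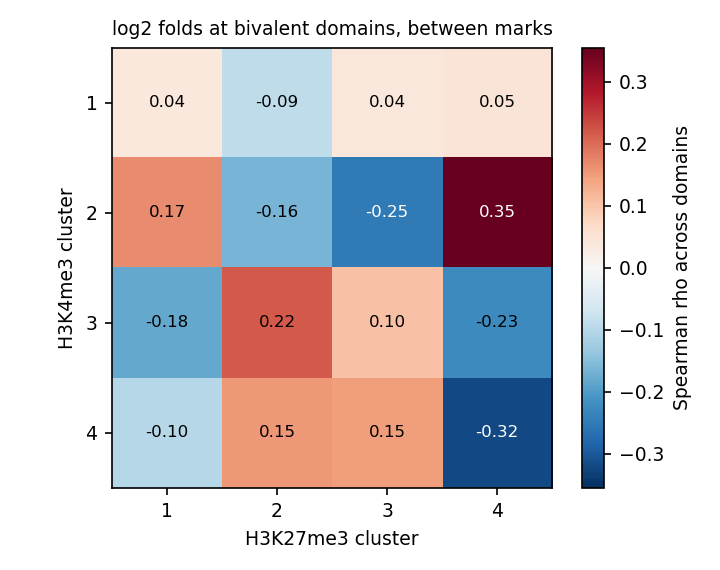
Spearman's rho across 19659 bivalent domains between the log2 fold of each H3K4me3 cluster (rows) and of each H3K27me3 cluster (columns), with its value in each field and in colour. H3K27me3 cluster 4 has the largest values of both signs, 0.355 with H3K4me3 cluster 2 and -0.320 with H3K4me3 cluster 4, without adjustment for the read level of the domains.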

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

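The share of H3K4me3 cluster 3 was 17.1% of cells in the third of the 5 sets of libraries, against 14.2 to 15.0% in the other 4 sets. Its distance from the nearest other set was 0.737 of the whole range, which is far for 5 values. Chance alone gives such a value in about 1 of 20 groups, and 6 measures were looked at in this way. The other 5, namely the cells and the median counts per set and the shares of the other 3 clusters, had no set that far from the rest.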

How the results depend on the processing

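Of 52 values recomputed for 12 results, 27 stayed within 1.5 times (counts), the confidence interval (medians) or the bootstrap range (correlations), and 25 moved. For cell clusters only the number of clusters was compared, not which cells they held. Values that stayed therefore include H3K4me3 clusters from principal components (adjusted Rand index 0.019) and clusters from thinned cells (0.186 and 0.327). The settings that left out the highest domains, kept full-width domains, thinned cells before clustering or used held-out folds for pairs of clusters were chosen after seeing the data. For each change below the cause was not tested, except where the setting itself counts fewer reads or regions. Median counts per cell were 1712 (H3K4me3) and 8087 (H3K27me3) on autosomes, and 1654.5 and 7677 with each region counted once. The overlap fell to 14815 regions when weak regions were left out. The correlation of levels was 0.017 without length correction and 0.075 in full-width domains. As Pearson's r of log2 values per kb it was 0.651. That value keeps the division by domain length, and with it the term that both marks share. Domains dominated by H3K4me3 and H3K27me3 numbered 5595 and 19 when scaled to all regions, and 4152 and 6590 at a ratio of 2. Region reads and domain reads were not counted alike, which by itself shifts the first 2 of these numbers towards H3K4me3. Median variance ratios for H3K4me3 and H3K27me3 were 1.021 and 1.011 in cells thinned to 500 domain reads (rho 0.004), over 3042 domains that had 1.047 and 1.045 (rho 0.058) in the same cells without thinning. Without the deepest 10% of cells they were 1.042 and 1.038 over 16825 domains, which had 1.045 and 1.043 in all cells. Binarised counts gave 0.997 and 1.001 (rho -0.086), but a 0 or 1 has the binomial variance however much cells differ, so this setting says nothing about stability, nor does its value of 0.98 for the named domain on chromosome 10 from 41714400. At a mean of at least 0.05 reads the H3K27me3 median was 1.042. H3K4me3 gave 2 clusters at resolution 0.3, and H3K27me3 gave 7 at resolution 1. The correlation of variation between clusters was 0.095 at resolution 1 and 0.002 for random clusters.

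Other settings that gave 4 clusters had adjusted Rand indices with the main clusters of 0.575 to 0.666 for H3K4me3 and 0.443 to 0.643 for H3K27me3. Thinned cells gave 3 clusters for each mark, with indices of 0.186 and 0.327, and principal components gave 3 and 5, with 0.019 and 0.434. Of the named folds, 11 of 12 for H3K4me3 and 7 of 12 for H3K27me3 had a held-out value inside their interval. No paired analysis was possible because the H3K27me3 tables carry no library names, so no H3K27me3 cell can be tied to a numbered library. Depth limits the named domains dominated by H3K27me3, which rest on 25 to 37 H3K4me3 reads, and the leading regions of H3K4me3 cluster 1, with 19 to 25 reads in all other cells.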

Other observations

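The tests of gene-dense chromosomes, of the number of clusters in simulated cells and of shared domains were chosen after the result was seen, and the others before.

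H3K4me3 regions inside and outside H3K27me3 territory differed in level. The 24355 autosomal H3K4me3 regions that overlap an H3K27me3 region were 47.3% of regions but held 39.1% of reads, with a median of 23.6 reads per 1000 cells (14.2 to 39.1). The 27117 other regions had a median of 30.6 (18.7 to 65.4). Their levels also varied less between clusters, with a median SD of log2 CPM of 0.328, against 0.401 in overlapping regions, among regions with at least 100 reads. Regions with fewer reads have a larger SD from counting alone, so part of this gap can arise from level. For H3K27me3 the order was the opposite for level, with a median of 1827 reads in regions that touch an H3K4me3 region and 1589 in the rest, and the same for variation, with a median SD of 0.230 against 0.202.

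A hypothesis was that H3K4me3 regions specific to a cluster overlap H3K27me3 regions more or less often than other regions. For each cluster the 500 regions with the largest held-out fold were set against 10000 random lists matched on read level. In cluster 2, 61.2% of them overlapped an H3K27me3 region, above the 95% range of 42.8 to 51.8% in matched lists. In cluster 4 the share was 47.6%, below its range of 48.4 to 57%, and clusters 1 and 3 lay inside theirs with 48.8% and 45.4%. The share thus lay outside the range in 2 clusters, and the read level of the regions does not account for it. What sets cluster 2 apart stays open. No annotation of the build was used, and few regions were strongly higher in that cluster, so its cell type was not tested.

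The clusters of H3K27me3 differed in depth, and a candidate explanation is that depth itself sets them. Clusters made after thinning each cell to 3000 counts had an adjusted Rand index of 0.327 with the main ones, between the bounds of 0.2 and 0.4 set in advance for and against this. Thinning also left out shallow cells, and leaving out the shallowest 25% of cells without thinning already gave 0.443, so depth cannot be told apart from other sources. The H3K4me3 clusters also differed in depth. Their index after thinning to 1000 counts was 0.186, under the bound of 0.2 that was set for H3K27me3, against 0.633 without the shallowest 25% of cells. Depth may therefore set part of the H3K4me3 clusters too, but thinning also discards reads, and the effect of that loss was not tested apart from depth. For H3K27me3, a different share of reads from gene-dense chromosomes cannot be told apart either. Over 22 autosomes the density of H3K4me3 regions had a rho of -0.717 with the median fold of the largest cluster, but 0.526 with that of the deepest. H3K4me3 clusters 1, 2 and 3 had values of similar size, -0.694, 0.642 and 0.722, and cluster 4 had -0.214, so this stays open for H3K4me3 too. The held-out folds of clusters were also related to the total reads of a region. For H3K4me3 clusters 1 to 4 rho was -0.389, 0.228, 0.320 and -0.019. For H3K27me3 clusters 1 to 4 it was 0.056, 0.257, -0.511 and -0.353. Clusters may therefore differ in how reads divide between weak and strong regions, and the cause was not tested. Chance structure in the counting of independent reads is argued against, since simulated cells with the same depths and no groups gave 1 cluster, against 4 in the data. The index between odd and even chromosomes that was planned for this was void, because it is 1.0 by definition when there is 1 cluster. The simulation held no duplicate reads and no reads counted in more than 1 overlapping window, so it cannot decide on noise of these kinds. No biological explanation was tested.

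Cluster profiles of the marks were related at bivalent domains, most strongly between H3K4me3 cluster 2 and H3K27me3 cluster 4 (rho 0.355, and 0.277 with folds from cells clustered without the domain's own chromosome). H3K27me3 cluster 4 was poorly found again from odd-numbered or even-numbered autosomes, with Jaccard indices of 0.38 and 0.27, so this pair may not stand for a fixed group of cells. The density of H3K4me3 regions around a domain, with the chromosome, is argued against as the cause, since rho given both was 0.361. Counting noise between random groups of cells is argued against too, since the largest rho of any pair in 100 random assignments was 0.028 in size. Random assignment removes all structure from the clusters. It therefore cannot tell whether real but unrelated clusters of each mark would give such a rho by chance. The read level of the domains stays open, because rho given the level in both marks was 0.188, and the pair of H3K4me3 cluster 2 and H3K27me3 cluster 3 was then the strongest with -0.201. With folds from cells clustered without the domain's own chromosome, that pair had a rho of 0.092, without adjustment for level. This value joins -0.061 on odd-numbered and 0.25 on even-numbered chromosomes. On the even-numbered ones the folds of H3K27me3 clusters 3 and 4 came from the same group of cells. The value therefore does not show a change of sign for cluster 3. Cell types shared by both pools are a biological explanation that was not tested here.

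Many of the domains with the most reads were shared by both marks. Of the 20 with the most reads in each mark, 14 were shared, with a median ratio of shares of 0.684. The domain on chromosome 1 from 143641500 to 143644499 was not, with 13 times the median count in H3K4me3 and 2 times in H3K27me3. The domain on chromosome 1 from 121184300 to 121187199 had 264.8 times the median H3K4me3 count and the highest count in H3K27me3 too, and those on chromosomes 6 and 7 named for their variation had 107.8 and 80.5 times the median H3K4me3 count. Reads that map there whatever the antibody cannot be told apart from a true level of both marks, because the number of shared domains only restates what was seen and no control without antibody was used here. The 11 domains above 10 times the median in both marks held 1.79% of H3K4me3 and 2.74% of H3K27me3 domain reads.

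H3K4me3 cells were not spread over libraries and barcodes as Poisson counting gives, and the cause was not tested. The 50 libraries with no cell in the table sat at the same 10 title positions in all 5 sets. Cells per library spread less than Poisson counting gives, with an SD of 2.86 against 4.26, and cells per barcode spread more, with 81.2 ± 18.5 (SD, n = 96 barcodes) against a Poisson SD of 9.0. Depth varied little by library, which took 7.1% of the variance of log2 counts per cell against 5.5% expected by chance. The share of cluster 4 had an SD of 3.5 percentage points between barcodes, against 3.3 from counting, and the other clusters lay at or under the counting SD.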
